A study of Glycine max with 102 samples.

How the data were processed

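RNA was measured in leaves of 102 soybean accessions at the V2 stage, when plants were 18 days old, with 1 library per accession. The labels describe TRIzol extraction and a stranded TruSeq kit used in reduced volumes. Of the 102 libraries, 41 came from parents of soyNAM, a nested association mapping population, and 61 from milestone cultivars, which are cultivars of note in the history of the crop.

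The values are FPKM per gene as deposited by the authors, in a table of 56044 gene IDs, of which 3099 were above 0 in no library. According to the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned with STAR 2.4.1c and quantified with Cufflinks 2.2.1. Apart from a version suffix on the deposited gene IDs, the genome build and the annotation are not stated in the sources used here. Filters on reads and the use of strand in quantification are not given there either. The depth of each library is unknown, because FPKM from Cufflinks keeps no read counts, so no counting interval and no detection floor is given. The sum of FPKM per library ran from 459817 to 864712. A value of exactly 0 can be a failed estimate: of 803 genes with a median of at least 100 FPKM, 4 had any value of 0, in 17 values. Without a statement on strand, reads of overlapping or antisense genes cannot be told apart. Near-identical copies, among them the LHY pairs, the chalcone synthase family, IFS1 and IFS2, and the copies of the rhg1 repeat, can share reads.

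Columns numbered 1 to 61 were taken as milestone cultivars, and the columns with the prefix NAM together with the column Parent as soyNAM parents. The table does not tie a column to a named cultivar beyond that, and 0 columns were left unused. The soyNAM parents were divided into 18 elite lines, 15 LG lines, which are breeding lines of diverse ancestry, and 8 PI lines, which are plant introductions. This division used the public family numbers of the population, 2 to 23 with Parent for elite, 24 to 39 for LG and 40 to 64 for PI. Those numbers are general knowledge and do not stand in the labels, although the sizes of the classes are those of the cultivar labels. The column Parent was taken as the hub parent IA3023 on the same ground.

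Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, and files were read with the data.table package, version 1.17.8. Genes with a mean of at least 1 FPKM over the 102 libraries were tested, which left 30101. A fold change on the log2(FPKM + 1) scale understates the change of genes with low values. Moderated statistics with a mean trend were used, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The comparison of the collections used 2 groups, and the other 3 comparisons were contrasts of a model with the 4 classes as groups. Each accession had 1 library, so a p-value measures a difference against the spread between accessions. In the contrasts of the 4 classes that spread was pooled over all 102 libraries, milestone cultivars included. Differences of library measures between the collections were tested with 2-sided permutation tests of 100000 resamples.

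The functions were tested on simulated data in which 200 genes were changed, 100 of them by 1.5-fold and 100 by 2-fold. For soyNAM parents against milestone cultivars, 93% of the genes changed by 1.5-fold and 99% of those changed by 2-fold were recovered, with 12 false calls. For LG against elite lines the shares were 79% and 90% with 3 false calls, for PI against elite lines 68% and 91% with 8, and for elite lines against milestone cultivars 88% and 96% with 9. Each of these runs tested 30101 genes. The simulated noise was normal and independent between genes and libraries, and no simulated library stood apart. The rates therefore do not cover the shared structure of the real libraries described below.

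The IDs of 7 lists were fixed before the data were examined: flowering and maturity, cyst nematode resistance, pigment and shape loci, isoflavonoid synthesis, leaf nitrogen storage, seed storage and nodule. Locus names come from published assignments known beforehand, since the table holds IDs only and 0 of the 56044 IDs matched the reference table of names. Lists defined by words in gene descriptions were left out for that reason. The 4 lists with at least 5 genes past the filter were tested with camera of limma at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry. Genes were named by a rule fixed at the same time: all genes of the lists, and in each comparison the 12 largest rises and 12 largest falls past the threshold. Because IDs outside the lists carry no names, at most 2 in each direction are printed.

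Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01 FPKM, no filter, a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile normalization, a principal component of the residuals as a covariate, robust moderation and a rank-sum test. Further ones left out the 5 libraries least similar to the others, the column Parent or each PI line in turn, or fitted only the groups compared. The removal of Parent and NAM10 together, and that of NAM29 and NAM48 with the 5 least similar libraries, were added after the data had been seen. Ratios at the rhg1 locus in the donor accession of that repeat and the similarity of pedigree pairs are not analysed here, because no column can be tied to those cultivars.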

Results

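Transcript levels were measured in leaves of 102 soybean accessions, 41 soyNAM parents and 61 milestone cultivars. In all 102 libraries 20033 genes reached 1 FPKM, and 44246 did so in at least 1 library. The soyNAM parents had 28062 ± 456 genes at 1 FPKM or more (SD, n = 41), fewer than the 29290 ± 348 in the milestone cultivars (n = 61; permutation p = 1e-05, the smallest the permutations can give). The 50 highest genes held 20.7% ± 2.96 of the FPKM in soyNAM parents and 20.6% ± 2.23 in milestone cultivars (permutation p = 0.935). Summed FPKM did not separate the collections either, at means of 692938 and 691756 (permutation p = 0.935). The first principal component held 35.3% of the variance and separated the collections with no overlap, from -64.89 to -20.91 in milestone cultivars and from 34.06 upwards in soyNAM parents.

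**Figure D1:**
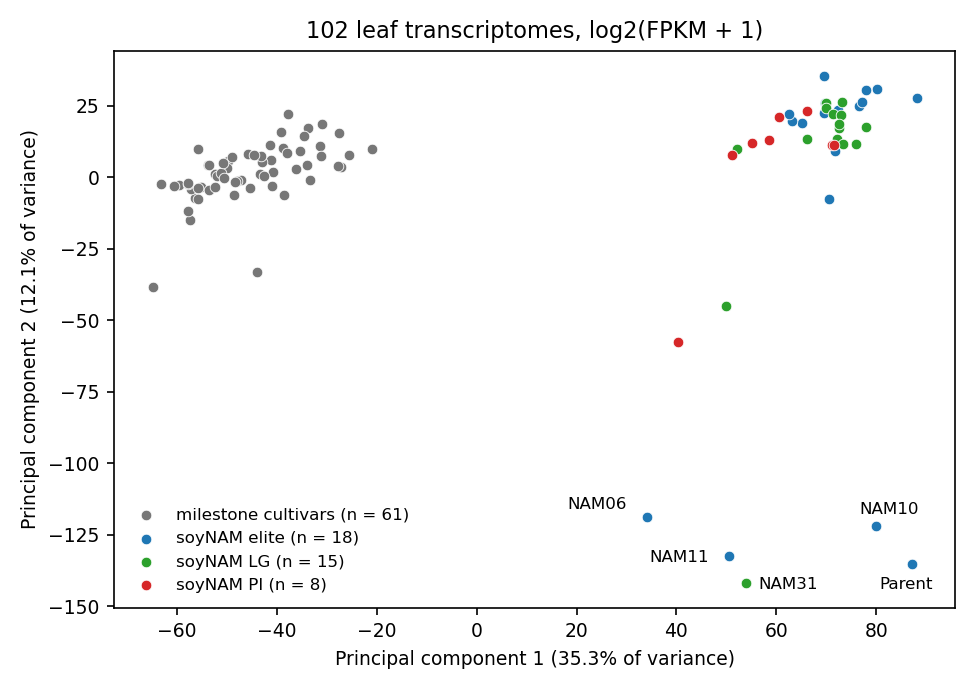
Each point is 1 library, placed by its scores on the first and second principal components of log2(FPKM + 1) and coloured by class. The collections lie apart along the first component, and 5 named soyNAM libraries lie between -119 and -142 on the second.

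Transcripts of the circadian clock set a few soyNAM libraries apart. LHY1a, LHY1b, LHY2a and LHY2b encode MYB repressors that peak around dawn. In the library Parent these genes were at 2.06, 1.57, 0.447 and 0.196 FPKM, and in NAM10 at 2.58, 1.97, 0.277 and 0.239 FPKM, against medians of 391, 153, 99.6 and 221 FPKM in the soyNAM parents other than these and NAM31, NAM11 and NAM06. J, the homologue of the evening gene ELF3, stood at 47.5 FPKM in Parent and 53.6 in NAM10, against a median of 5.91. E2, the homologue of GIGANTEA, stood at 94.5 and 94.7 FPKM against 37.1. The clock gene PRR3b (Glyma.12G073900) stayed within the range of the other 100 libraries, at 34.1 FPKM in Parent, the lowest soyNAM value, and 41.2 in NAM10, against a soyNAM median of 52.1 FPKM. The libraries NAM31, NAM11 and NAM06 had intermediate LHY2b levels of 40.8, 49.7 and 36.4 FPKM, as did NAM48 and NAM29 at 46.1 and 53.97 FPKM. J was not high in NAM31, NAM11 and NAM06, at 4.29, 3.79 and 2.71 FPKM, and E2 stood at 55.98, 65.3 and 38.03 FPKM. Parent, NAM10, NAM31, NAM11 and NAM06 also had the lowest median Spearman correlations with all others, between 0.662 and 0.773, against a median of 0.896 over all libraries. Their libraries differed in composition as well, since the 50 highest genes held 12.6% of the FPKM in Parent, 13.5% in NAM10, 13.7% in NAM31 and NAM11 and 15.03% in NAM06, against a median of 20.9%. Summed FPKM was 459817 in Parent, 519785 in NAM10, 564617 in NAM31, 511567 in NAM11 and 601047 in NAM06, against a median of 700221. The milestone library 60 was also low, at 14.1% and 529002.

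**Figure D2:**
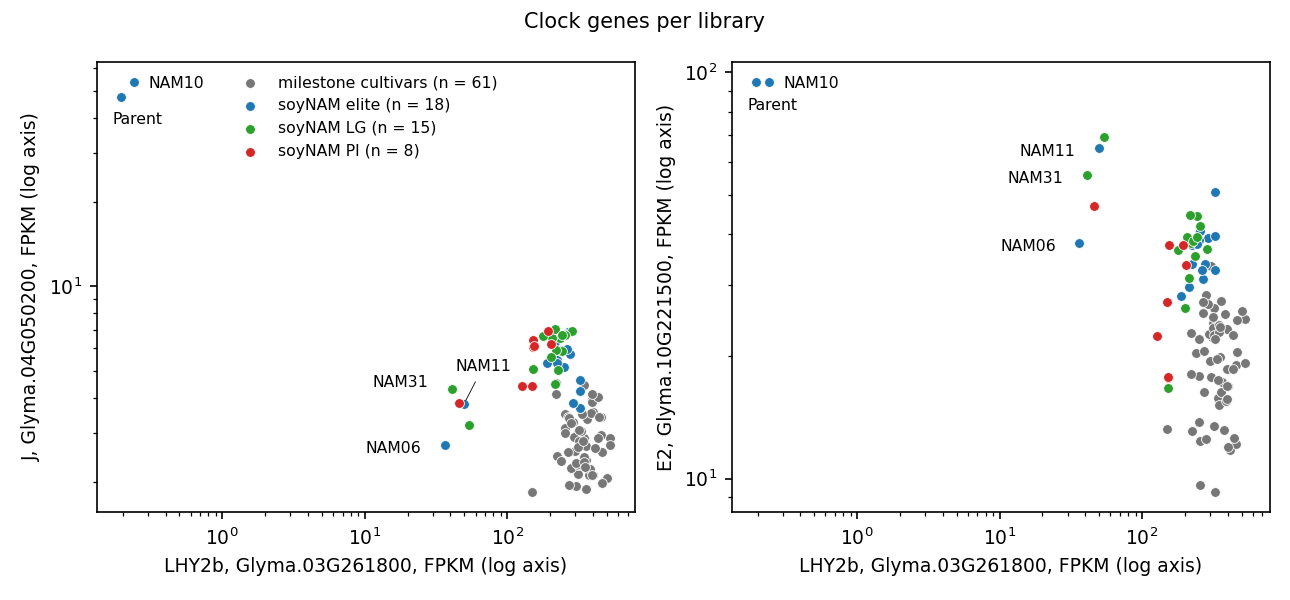
Each point is 1 library, with LHY2b on the horizontal axis and J (left) or E2 (right) on the vertical axis, all in FPKM on log axes, coloured by class. Parent and NAM10 combine LHY2b levels of 0.196 and 0.239 FPKM with J levels of 47.5 and 53.6 FPKM.

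The comparison of soyNAM parents with milestone cultivars asked how leaf expression differed between the 2 collections of the series. FT2a (Glyma.16G150700), a florigen gene that promotes flowering, averaged 6.09 ± 3.18 FPKM (SD, n = 41) in soyNAM parents and 0.499 ± 0.873 FPKM (n = 61) in milestone cultivars, a log2 fold change of 2.19 (SE 0.141). FT5a (Glyma.16G044100), the other florigen gene followed, averaged 2.36 ± 1.99 against 0.376 ± 0.539 FPKM. P1 (Glyma.09G278000), a locus for pubescence, went the other way, with 13.7 ± 17.6 FPKM in soyNAM parents and 486 ± 250 FPKM in milestone cultivars, a log2 fold change of -5.46 (SE 0.221). CHS1 (Glyma.08G109400), which encodes the chalcone synthase that opens flavonoid synthesis, averaged 0.730 ± 0.802 against 8.10 ± 4.08 FPKM. In limma with Benjamini-Hochberg adjustment the adjusted p was 1.3e-27 for FT2a, 3.4e-13 for FT5a, 9.5e-43 for P1 and 6.1e-34 for CHS1.

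Of the 18 genes on the flowering and maturity list 12 passed the filter, and 5 of these were higher in soyNAM parents and 5 lower. Adjusted over the list alone the call count was also 10. Among all 30101 genes tested 74.8% were called in this comparison. Call counts near that share, on this list and those below, do not set a list apart. Besides the florigen genes, E2 (Glyma.10G221500) was higher at 39.8 ± 16.5 against 19.5 ± 5.28 FPKM, and the phytochrome A gene E4 (Glyma.20G090000) at 35.3 ± 8.87 against 23.6 ± 2.91 FPKM. J (Glyma.04G050200) was higher by a log2 fold change of 0.87, at medians of 5.89 and 2.87 FPKM. LHY2b (Glyma.03G261800) was lower, at 193 ± 88.2 against 342 ± 80.0 FPKM and a log2 fold change of -1.24. LHY2a, LHY1a and LHY1b were lower by log2 fold changes of -0.60, -0.51 and -0.40, and the stem termination gene Dt2 by -0.33. PRR3b and the phytochrome A gene E3 did not pass, at -0.07 and 0.00. FT2a lay below 0.1 FPKM in 26 of 61 milestone cultivars and in 1 of 41 soyNAM parents. As a list these genes had a median log2 fold change of -0.03, which was 0.01 after quantile normalization, a mean of 0.21 and an upward sign in camera, whose adjusted p was 0.276 (adjusted p = 0.599 with an estimated correlation). The LHY genes moved with the 5 libraries that stand apart. LHY1b lost its call without Parent alone (-0.27, adjusted p = 0.0889), and both LHY1a and LHY1b lost theirs in the rank-sum test. Without the 5 libraries, LHY1a and LHY1b no longer passed (-0.05 and -0.01), while LHY2a (-0.20, adjusted p = 0.0158) and LHY2b (-0.71, adjusted p = 8.6e-11) still did in limma. With NAM29 and NAM48 left out as well, LHY2a lost its call (-0.14, adjusted p = 0.0790) and LHY2b did not (-0.59).

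On the list of pigment and shape loci, 5 of 11 genes passed the filter, with 1 higher and 3 lower, and the same 4 in number when adjusted over the list alone. Among the stay-green loci, G (Glyma.01G198500) was higher in soyNAM parents at 258 ± 65.0 against 129 ± 25.1 FPKM. D2 (Glyma.11G027400), which acts in chlorophyll breakdown, was lower at 6.34 ± 4.54 against 18.4 ± 7.60 FPKM. The flavonoid 3'-hydroxylase gene T (Glyma.06G202300), which sets pubescence colour, was lower with a log2 fold change of -0.97. The adjusted p in limma with Benjamini-Hochberg adjustment was 1.3e-25 for G, 4.7e-22 for D2 and 1.9e-07 for T. D1 did not pass at -0.08, but did without the 5 libraries that stand apart (-0.24). The list's camera adjusted p was 0.276, and the adjusted p = 0.493 with an estimated correlation.

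On the isoflavonoid list 5 of 7 genes passed the filter, 3 of them lower and 0 higher in soyNAM parents, and 3 adjusted over the list alone. CHS8 (Glyma.11G011500) was lower at 10.7 ± 31.2 against 18.1 ± 6.08 FPKM (log2 fold change -1.56), and the isoflavone synthase gene IFS1 (Glyma.07G202300) at medians of 25.5 against 38.4 FPKM (-0.62, limma adjusted p = 0.0074). CHS7 and IFS2 did not pass (-0.42 and 0.20). Single soyNAM libraries reached 323 FPKM for CHS7, 199 for CHS8 and 208 for IFS2. Without the 5 libraries that stand apart, 4 genes of the list were lower, CHS7 now among them at -0.93. Camera gave an adjusted p of 0.276 for the list, and an adjusted p = 0.493 with an estimated correlation.

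The vegetative storage protein genes, which hold nitrogen in leaves, went opposite ways. VspA (Glyma.07G014500) was lower in soyNAM parents at 1548 ± 1112 against 2025 ± 1089 FPKM (-0.49, limma adjusted p = 0.0249), and VspB (Glyma.08G200100) was higher at 256 ± 373 against 117 ± 96.2 FPKM (0.92, limma adjusted p = 0.0068). Both passed also when adjusted over the list alone, which made 2 of 2 genes. Without the 5 libraries that stand apart VspA no longer passed (-0.34, adjusted p = 0.0806 in limma), nor did it with the mean of the 3 soyNAM classes in place of the whole collection (-0.41).

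On the list of loci for resistance to the soybean cyst nematode 5 of 6 genes passed the filter, with 2 higher and 1 lower in soyNAM parents, and 4 calls when adjusted over the list alone. Within the rhg1 repeat, a tandem segment whose copy number is known to vary among cultivars, the alpha-SNAP gene (Glyma.18G022500) had a log2 fold change of 0.60 and the amino acid transporter gene (Glyma.18G022400) one of 0.57. Their medians differed little, at 26.8 against 24.2 and 5.15 against 4.84 FPKM, while their means were 69.4 ± 92.6 against 31.4 ± 32.5 and 16.8 ± 26.6 against 6.25 ± 8.32 FPKM. SNAP11 (Glyma.11G234500), an alpha-SNAP paralogue, was lower at 12.8 ± 3.08 against 15.7 ± 3.27 FPKM. The WI12 gene of the repeat (0.53, limma adjusted p = 0.051) and the serine hydroxymethyltransferase gene at Rhg4 (0.14) did not pass, and under both other scalings 3 genes of the list were higher. The transporter gene no longer passed in the rank-sum test (adjusted p = 0.110), and the genes WI12 and Rhg4 gained calls without Parent (0.54 and 0.20, limma adjusted p = 0.0479 and 0.0370). Camera gave an adjusted p of 0.618, and an adjusted p = 0.691 with an estimated correlation.

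Across all genes, limma with Benjamini-Hochberg adjustment called 22508 of 30101, with 11132 higher and 11376 lower in soyNAM parents, at a median absolute log2 fold change of 0.29. Which direction held more genes depended on scaling, with 12655 higher and 10187 lower after quantile normalization and 11593 and 10953 under median-of-ratios scaling. A fold of at least 2 was reached by 1037 higher and 1881 lower genes. Without overlap between the collections, 75 genes were higher in every soyNAM parent and 236 lower, where chance would give 1.1e-24 genes. Outside the lists, the largest falls were in Glyma.15G239200 (0.527 ± 1.41 against 412 ± 194 FPKM) and Glyma.15G239600 (8.53 ± 18.9 against 381 ± 160 FPKM). The largest rises were in Glyma.19G102400 (median 34.5 against 0.968 FPKM) and Glyma.17G186400 (29.3 ± 16.5 against 1.61 ± 5.94 FPKM). The labels give no batch or date of growth, so a batch that coincides with the collection and the collection itself cannot be told apart.

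**Figure D3:**
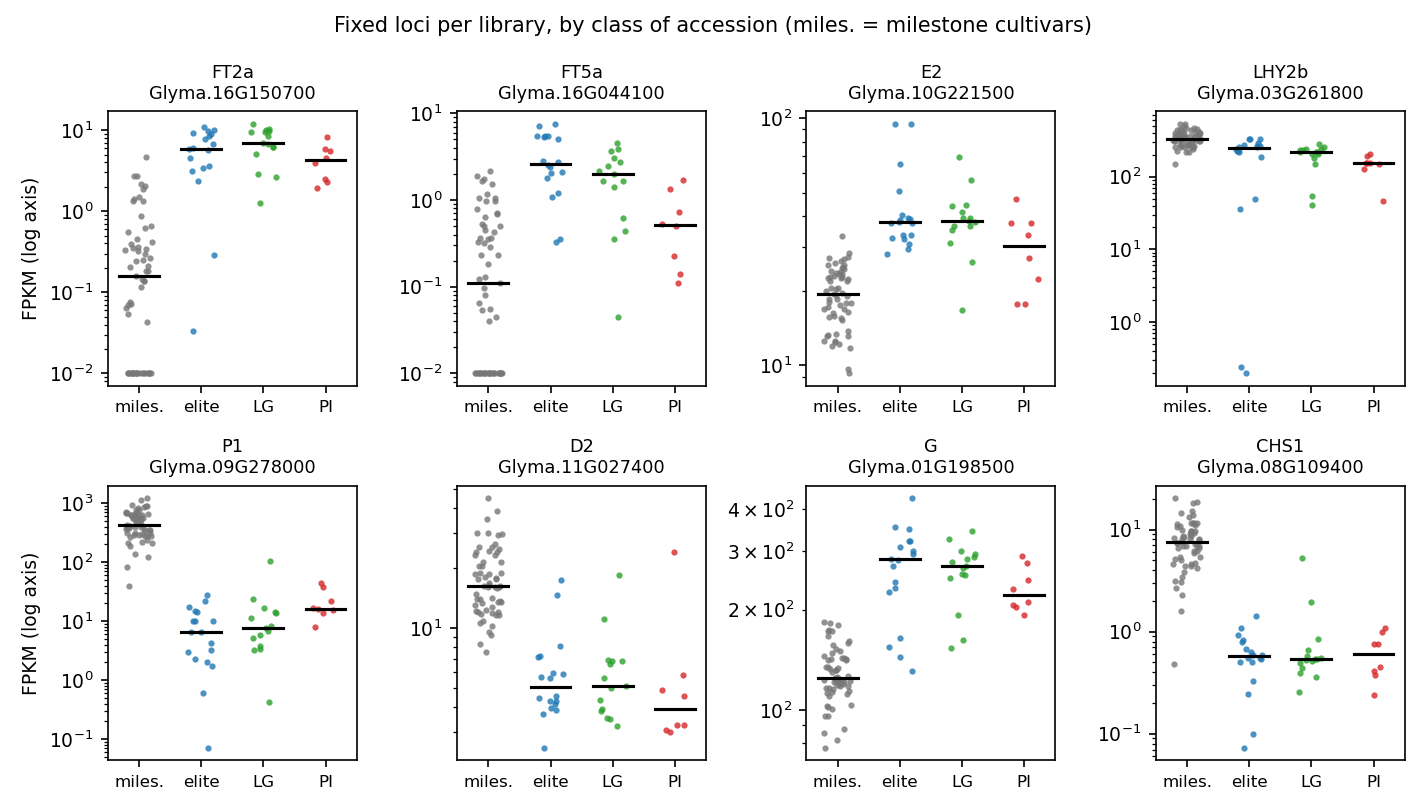
Each panel shows 1 fixed locus in FPKM on a log axis, with 1 point per library by class and a bar at the class median, and values below 0.01 FPKM are drawn at 0.01. FT2a, FT5a, E2 and G lie higher and LHY2b, P1, D2 and CHS1 lower in the soyNAM parents.

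LG lines and elite lines, both within soyNAM, differed in few genes, and their assignment to classes rests on family numbers that the labels do not state. Among 30101 genes, limma with Benjamini-Hochberg adjustment called 3 higher and 5 lower in LG lines, and 2441 genes had an unadjusted p under 0.05. Glyma.05G175700 fell to 55.7 ± 27.1 FPKM in LG lines (SD, n = 15) from 122 ± 51.7 FPKM in elite lines (n = 18), with a log2 fold change of -1.19 and a limma adjusted p of 0.0018. Glyma.07G265900 was lower too, at 4.38 ± 1.21 against 6.95 ± 2.03 FPKM, while Glyma.18G184900 at 9.99 ± 1.67 against 5.94 ± 2.92 FPKM and Glyma.08G091600 at 13.1 ± 1.69 against 10.7 ± 1.25 FPKM were higher. What these 4 genes encode is not given in the table.

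No gene on any list was called between LG and elite lines over all genes tested, and adjusted over the list alone 3 of the 5 nematode resistance genes were called, with 0 on the others. Those 3 were the rhg1 genes, with log2 fold changes of -0.96 for the transporter gene, -0.94 for the alpha-SNAP gene and -1.03 for the WI12 gene, and limma adjusted p over all genes of 0.396, 0.372 and 0.522. The alpha-SNAP gene averaged 40.8 ± 48.7 FPKM in LG lines and 113 ± 121 FPKM in elite lines. Among flowering genes FT5a stood at 2.05 ± 1.37 against 3.38 ± 2.26 FPKM and E4 had a log2 fold change of 0.30, which did not pass (adjusted p of 0.541 and 0.421 in limma). For P1 the log2 fold change of 0.47 had a 95% interval from -0.26 to 1.19. The storage protein genes VspA and VspB also did not pass, at 0.30 and 0.50.

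The camera adjusted p between LG and elite lines was 0.336 for flowering, 0.155 for nematode resistance, and 0.931 for both isoflavonoid and pigment lists. The corresponding values were adjusted p = 0.821, 0.442, 0.930 and 0.930 with an estimated correlation. The isoflavonoid median of -0.01, 0.03 after quantile normalization, and its mean of 0.04 differed in sign, and for pigment loci the median of 0.00 and mean of 0.04 stood against a downward sign in camera. A fit of only these classes called 0 genes and a rank-sum test 1, while 109 genes passed without the 5 libraries that stand apart and 54 without these, NAM29 and NAM48. Without the 5 libraries the flowering median went from 0.21 to -0.21, LHY1a, LHY1b, LHY2a and LHY2b from 0.63, 0.48, 0.47 and 0.61 to -0.27, -0.34, -0.33 and -0.38, and 5 flowering genes were called adjusted over the list alone, though 0 over all genes in limma. All 4 named genes lost their calls in the fit of only these classes and in the rank-sum test.

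Between PI and elite lines, with the same limit on the classes, 1037 genes were called, among them the florigen gene FT5a. A fit of only these classes called 290. Of 100 splits into groups of the same sizes, the real one included, 5 reached at least 1037 genes, so chance is not excluded for this count. FT5a averaged 0.662 ± 0.587 FPKM in PI lines (SD, n = 8) and 3.38 ± 2.26 FPKM in elite lines (n = 18), a log2 fold change of -1.26 with a limma and Benjamini-Hochberg adjusted p of 8.3e-04. The alpha-SNAP gene at rhg1 was lower in PI lines, at 25.6 ± 4.37 against 113 ± 121 FPKM (-1.26, limma adjusted p = 0.0373), and a median of 23.9 FPKM in PI lines. Elite values ran from 18.9 FPKM in NAM04 to 402 in NAM10, so the elite mean rests on the high libraries. P1 was higher, at 21.7 ± 12.6 against 8.72 ± 7.91 FPKM (1.56, limma adjusted p = 0.0302). Across 30101 genes 645 were higher and 392 lower, of which 36 and 36 reached a fold of at least 2.

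On the flowering list 1 of the 12 measured genes was called in PI against elite lines, FT5a, and 2 adjusted over the list alone, the other being E2 at 30.1 ± 10.6 against 44.3 ± 20.2 FPKM (-0.52, limma adjusted p = 0.0876). FT2a did not pass at -0.22. On the nematode resistance list 1 of 5 was called, and 3 adjusted over the list alone, since the transporter gene (-1.28) and the WI12 gene (-1.26) had limma adjusted p of 0.0533 and 0.166 over all genes. On the pigment list P1 was the 1 call of 5, and also the 1 call adjusted over the list alone. On the isoflavonoid and the nitrogen storage lists 0 genes were called in limma either way, with IFS1 at 0.88 and VspA at 0.66. Camera adjusted p was 0.298 for flowering, 0.298 for nematode resistance, 0.818 for pigment loci and 0.865 for isoflavonoid genes, and adjusted p = 0.777, 0.687, 0.810 and 0.909 with an estimated correlation. The pigment median of -0.08 and mean of 0.25 differed in sign, with camera upward, and the isoflavonoid median of 0.03 was -0.02 after quantile normalization.

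Outside the lists, Glyma.09G186200 (62.2 ± 28.6 against 14.5 ± 26.5 FPKM) and Glyma.09G186300 (16.4 ± 7.61 against 3.71 ± 6.64 FPKM) had the largest rises in PI lines. The largest falls were in Glyma.06G177600 (25.6 ± 36.3 against 182 ± 368 FPKM) and Glyma.03G046800, which was at most 2.78e-08 FPKM in the PI lines and averaged 9.92 ± 9.36 FPKM in elite lines. In 9 genes all PI lines lay above all elite lines and in 4 below, where chance would give 0.0385 genes.

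The 5 libraries that stand apart, 4 of them elite lines and 1 an LG line, weighed on the comparison of PI with elite lines. Without them 3515 genes passed, 6 of the flowering genes were lower, among them LHY2b at -0.92 where it had been 0.23 with all libraries, and P1 no longer passed (1.06, limma adjusted p = 0.0805), while the transporter gene at rhg1 gained a call (-1.31, limma adjusted p = 0.0231). With NAM29 and NAM48, which share the low LHY2b level, left out as well, 2491 genes passed, LHY2b was at -0.70, and the transporter gene passed (-1.30, limma adjusted p = 0.0418). The alpha-SNAP gene and P1 did not pass then, at -1.14 and 1.22 (limma adjusted p = 0.0532 and 0.0588). Leaving out 1 PI line at a time gave 499 genes without NAM42, 554 without NAM46, 527 without NAM50 and between 748 and 1142 otherwise. E2 gained a call without NAM48 (-0.62, adjusted p = 0.0410). The alpha-SNAP call ended without NAM40, NAM41, NAM42, NAM46, NAM50 or NAM54 (limma adjusted p from 0.0511 to 0.0772), and the P1 call without NAM40, NAM42 or NAM50 (0.0636 to 0.0951), and both ended in the rank-sum test and in the fit of only these classes. FT5a lost its call at a pseudocount of 0.01 FPKM (adjusted p = 0.161) and Glyma.03G046800 without any 1 of the PI lines, while Glyma.06G177600, Glyma.09G186200 and Glyma.09G186300 lost theirs in the fit of only these classes.

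Elite lines were also set against milestone cultivars, which leaves the LG and PI lines out of the comparison of the collections; these libraries are part of the first comparison, so the results are not independent of it. FT2a averaged 5.93 ± 3.33 FPKM in elite lines (SD, n = 18) against 0.499 ± 0.873 FPKM in milestone cultivars (n = 61), a log2 fold change of 2.11, and FT5a had a log2 fold change of 1.55. P1 averaged 8.72 ± 7.91 against 486 ± 250 FPKM (-5.94), and CHS1 0.608 ± 0.330 against 8.10 ± 4.08 FPKM. The adjusted p in limma with Benjamini-Hochberg adjustment was 1.1e-18 for FT2a, 1.4e-15 for FT5a, 2.6e-36 for P1 and 4.8e-25 for CHS1. Of 30101 genes, 10223 were higher and 10456 lower, and 1157 and 2022 of these reached a fold of at least 2. The balance turned with scaling, to 11639 higher and 9448 lower after quantile normalization and 10769 and 10015 under median-of-ratios scaling.

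Between elite lines and milestone cultivars 68.7% of all genes tested were called, and list counts near that share do not set a list apart. On the flowering list 5 of 12 genes were higher in elite lines than in milestone cultivars and 4 lower, 9 also when adjusted over the list alone. E2 was at 44.3 ± 20.2 against 19.5 ± 5.28 FPKM and LHY2b at a log2 fold change of -1.50. On the pigment list 1 was higher, G, and 3 were lower, P1, D2 at -1.44 and T at -0.90, and 4 adjusted over the list alone. On the isoflavonoid list 3 of 5 were lower, CHS1, CHS8 at -1.50 and IFS1 at -0.98, also 3 adjusted over the list alone. On the nematode resistance list the 3 rhg1 genes were higher, at 1.17 for the transporter, 1.19 for alpha-SNAP and 1.16 for WI12, and SNAP11 was lower at -0.37, which made 4 calls either over all genes or adjusted over the list alone. VspA was lower at -0.73 and VspB did not pass at 0.61, so 1 of 2 was called either way. Camera adjusted p was 0.279 for flowering, isoflavonoid and pigment lists and 0.402 for nematode resistance, and adjusted p = 0.515, 0.501, 0.501 and 0.515 with an estimated correlation. The flowering median of -0.04 and mean of 0.17 differed in sign, with camera upward.

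LHY genes again moved with the 5 libraries, 4 of which are elite lines. Without them LHY1a, LHY1b and LHY2a were at 0.20, 0.30 and 0.08 in place of -0.81, -0.60 and -0.80, and 7 flowering genes were higher and 1 lower. VspA then lost its call (-0.44), and VspB (1.23), CHS7 (-1.03) and D1 (-0.38) gained one, while the transporter gene lost its call in the rank-sum test (adjusted p = 0.104). Glyma.15G239200 and Glyma.15G239600 had the largest falls (-8.26 and -6.35), and Glyma.19G102400 and Glyma.17G186400 the largest rises (4.56 and 4.27).

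Levels of the rhg1 genes differed between single accessions more than between groups. In 9 libraries the transporter gene reached at least 4 times the median of its collection, between 26.2 and 89.9 FPKM, and these were 6 of 18 elite lines, 1 of 15 LG lines, 0 of 8 PI lines and 2 of 61 milestone cultivars. The share was 7 of 41 in soyNAM parents and 2 of 61 in milestone cultivars (2-sided Fisher's exact test p = 0.0282). Some libraries lay between. The ratios for the transporter, alpha-SNAP and WI12 genes were 2.25, 4.83 and 3.69 in NAM11. They were 2.14, 2.59 and 2.33 in milestone library 53, and 1.88, 2.68 and 2.29 in milestone library 48. The shares and the p-value depend on the cut, and other cuts were not tested. The alpha-SNAP gene did so in 10 libraries and the WI12 gene in 9, and 9 libraries did so for all 3 of these genes, where the highest number in 100000 permutations was 3 (permutation p = 1e-05, the smallest they can give). The list's other gene in the repeat, Glyma.18G022600, reached at most 1.06 FPKM, did not pass the filter and was left out of this count. Against medians of 0.0679 FPKM in soyNAM parents and 0.110 FPKM in milestone cultivars it reached that ratio in 9 libraries, of which 5 were among the 9 above and 4 were not. The genes Glyma.18G023100, Glyma.18G023200 and Glyma.18G023300, whose IDs follow those of the repeat, were taken as flanking genes. Each of these 3 reached that ratio in 0 libraries, with highest ratios of 2.87, 1.70 and 2.64. They do not follow directly on the last ID of the repeat, Glyma.18G022700, and IDs in between were not examined.

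**Figure D4:**
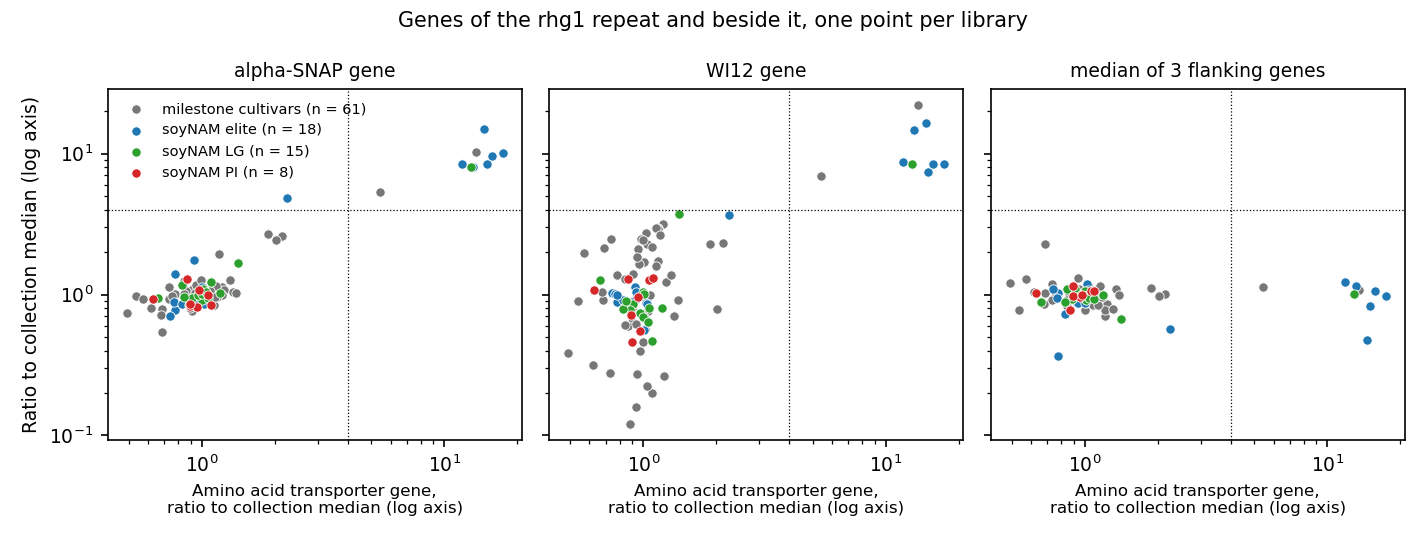
Each point is 1 library, with the ratio of the transporter gene to its collection median on the horizontal axis and that of the alpha-SNAP gene, the WI12 gene or the median of 3 flanking genes on the vertical axes, all on log axes. Dotted lines mark a ratio of 4, which 9 libraries reached for all 3 tested genes of the repeat and 0 libraries for a flanking gene.

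Markers of other tissues were near absent. None of the 7 seed storage genes and none of the 4 nodule genes passed the filter, so 0 genes of these lists were tested in limma. The highest value of a seed storage gene in any library was 3.79 FPKM, and that of a leghemoglobin gene 2.68 FPKM.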

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

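Chosen only after the result was seen were the tests of time of day, of a growth or library batch, of seed or nodule RNA and of the rhg1 repeat. The other tests of this part were stated before their results.

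Most genes differed between the collections, and chance is excluded as the reason: the real grouping gave 22508 genes, and the highest of the other 99 random splits gave 4, so 1 of 100 splits reached the real count. Scaling between libraries is argued against by the 22546 genes called under the scaling that called fewer. For the pedigree of the accessions alone, PI lines, the introductions, differed from elite lines by a median absolute log2 fold change of 0.133. The 100 sets of 8 milestone accessions differed from elite lines by 0.296 to 0.333. This argues against pedigree alone only if PI lines are as distant in descent from elite lines as milestone cultivars are. Such distance was not measured. Sampling at another time of day by as much as Parent and NAM10 is argued against by the median LHY log2 fold change of -0.13 without the 5 least similar libraries. The genes were unlike, with LHY1a at -0.05, LHY1b at -0.01, LHY2a at -0.20 and LHY2b at -0.71. With all libraries E2 and J were higher in soyNAM parents, the direction seen in Parent and NAM10. Their medians were 37.6 and 5.89 FPKM against 19.4 and 2.87 FPKM in milestone cultivars. A growth or library batch cannot be told apart from the collection, because 0 soyNAM libraries lay within the milestone range of the first principal component and the labels give no batch; a smaller difference in hour and the origin of the accessions together with such a batch also stay open.

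The libraries Parent and NAM10 stand apart, with 4 LHY genes lower than in the other 100 libraries and J and E2 high. RNA of seed or nodule tissue is argued against by summed FPKM of at most 0.552 over the seed storage and nodule genes in them. Sampling at another time of day cannot be told apart from other explanations, because LHY, J and E2 are the pattern itself, the hour is not in the labels, and for PRR3b, the clock gene outside the pattern, 0 of the 2 libraries lay outside the range of the others (34.1 and 41.2 FPKM against a soyNAM median of 52.1). A difference in library composition was not tested. The 50 highest genes held 12.6% of the FPKM in Parent and 13.5% in NAM10 against a median of 20.9%. They held 13.7% in NAM31 and NAM11, where LHY2b stood at 40.8 and 49.7 FPKM and J at 4.29 and 3.79. They held 14.1% in milestone library 60, and no milestone library was below 150 FPKM for LHY2b or above 4.52 for J. This argues against composition alone for the full pattern of Parent and NAM10, while a part in it stays open. A genetic difference at a clock locus and another growth condition were not tested either.

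The rhg1 genes vary together between accessions. A shift of the chromosome region that reaches the 3 flanking genes is argued against. For all 3 repeat genes that passed the filter, 9 libraries stood at 4 times the collection median or more, and 0 libraries did so for a flanking gene. The IDs of these flanking genes all follow the repeat, though not directly. Genes before the repeat and those between it and the flanking genes were not examined. More copies of the repeat in some accessions cannot be told apart from regulation shared by the 3 genes, because their joint rise is the pattern itself and copy number was not measured. The fourth gene of the repeat, Glyma.18G022600, reached that ratio in 5 of the 9 libraries, at levels too low to decide.

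Random splits were also drawn for the other comparisons, 100 for each. For LG against elite lines chance is not excluded, since 13 splits gave at least the 8 genes of the real grouping and the highest gave 6412. For PI against elite lines chance is not excluded either, with 5 splits at or above 1037 genes and a highest of 9627. Of the other splits 6 and 4 called more than 1000 genes, which points to a structure of the samples, the 5 libraries that stand apart. Without these 5, a random division of the remaining libraries is argued against for both. Only 1 split, the real one, reached 109 genes for LG lines (highest other 18), and 1 reached 3515 genes for PI lines (highest other 12). No splits were drawn with NAM29 and NAM48 left out as well. What else may coincide with the classes was not tested by the splits. For elite lines against milestone cultivars chance is excluded, with 1 split at 20679 genes and a highest other of 4974.

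In the PI lines, 37 measures were checked for a library whose gap to its nearest neighbour took an unusual share of the range of the 8 lines, and 9 exceeded the critical share of Dixon's test; chance alone does so in about 1 of 20 groups. NAM48 was low for LHY1a (140 FPKM against a median of 321 in the others, a share of 0.66) and for LHY2b (46.1 against 152 FPKM, 0.681). NAM48 was high for the stay-green gene D2 (23.99 against 3.27 FPKM, 0.712). In NAM48 the 50 highest genes held 16.7% of the FPKM, lower than in the other PI lines (0.537). Glyma.03G046800 was at 2.78e-08 FPKM in NAM48 against a median of 0, a share of 0.65 at a level near 0. NAM42 was low for IFS1 (6.505 against 30.7 FPKM, 0.575). NAM42 was also low for Glyma.09G186200 (0.0799 against 70.0 FPKM, 0.868) and for Glyma.09G186300 (0.0131 against 18.2 FPKM, 0.786). NAM50 was low for the transporter gene at rhg1 (3.23 against 4.91 FPKM, 0.571).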

How the results depend on the processing

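The removal of Parent and NAM10 together, that of NAM29 and NAM48 with the 5 least similar libraries, the counts of lists without the 5 least similar libraries and the switch-like genes within both collections were chosen after the data had been seen. The collections kept a count of genes within 1.5 times the reported one under every alternative run except a filter at a mean of 5 FPKM, which tests fewer genes and gave 12573 for soyNAM parents and 11596 for elite lines against milestone cultivars. LG against elite lines gave 8 genes as reported, 4 and 5 at pseudocounts of 0.1 and 0.01, 14 with no filter, 3 after quantile normalization (1 higher, 2 lower), 6 under median-of-ratios scaling (1 higher, 5 lower), 198 with a residual principal component as covariate, 1 in the rank-sum test, 109 without the 5 least similar libraries, 54 without these, NAM29 and NAM48, and 0 in a fit of only the groups compared in limma. PI against elite lines gave 1037 as reported, 2365 with the residual component, 669 in the rank-sum test, 3515 without the 5 libraries, 2491 without these, NAM29 and NAM48, and 290 with only the groups compared. Leaving out 1 PI line at a time gave 499 to 1142. The cause of these changes was not tested.

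In fry, a test of whether a list moves one way on balance, the adjusted p for soyNAM parents against milestone cultivars was 1.1e-05 for flowering, 6.8e-15 for isoflavonoid and 6.0e-24 for pigment lists. For elite lines against milestone cultivars it was 6.8e-04, 7.4e-10 and 6.7e-18, and 0.0042 for nematode resistance. Unlike camera, fry does not compare a list with other genes. Limma called 74.8% of all genes tested for soyNAM parents and 68.7% for elite lines against milestone cultivars. The flowering list had 5 genes higher and 5 lower in soyNAM parents. The fry p-values therefore do not set these lists apart from other genes, and no conclusion is drawn from them. The median number of genes expressed per library was 28985.5 at 1 FPKM and 15860.5 at 5 FPKM. Switch-like genes, 436 as reported, were 1185 with 2 FPKM as the upper level, 781 with 0.5 FPKM as the lower, 949 with 5 accessions on each side and 148 within both collections.

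Of 1919 alternative values for 132 gene results, 1779 stayed on their side of the threshold, 1707 of them with the same sign and 72 with a changed sign in a value that passed in neither fit. A further 47 gained and 76 lost a call with the same sign, and 17 changed direction with a call in at least 1 fit. Without the 5 libraries, PI against elite lines changed direction for Glyma.16G017400 (-0.66), Glyma.07G048500 (-0.77), Glyma.19G260900 (-0.73) and Glyma.03G261800 (-0.92), the 4 LHY genes, and without NAM29 and NAM48 too they were at -0.52, -0.65, -0.65 and -0.70. Elite lines against milestone cultivars changed for Glyma.16G017400 (0.20), Glyma.07G048500 (0.30) and Glyma.19G260900 (0.085), the same without NAM29 and NAM48 too, and for Glyma.07G048500 without Parent and NAM10 (0.043). SoyNAM parents against milestone cultivars changed for Glyma.16G017400 (0.025) and Glyma.07G048500 (0.056) without all 7. These alternatives all leave out Parent and NAM10, the 2 lowest libraries for each of the 4 LHY genes. No paired analysis was possible because the columns carry no replicate numbers, and the numbers of accessions give their order only. Not run were the rhg1 ratio in the donor accession of that repeat with its alternatives, the fits without that accession and the pedigree pairs, since no column can be tied to those cultivars. Depth is unknown, so whether a gene listed at 0 was absent cannot be decided.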

Other observations

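The count within both collections was chosen after the data had been seen, and the test of neighbours was stated before its result. Some genes were switch-like between accessions, at or above 5 FPKM in at least 10 of them and below 0.1 FPKM in at least 10. There were 436 such genes, and for 241 of them the share of accessions with the gene on, here at 1 FPKM or more, differed between the collections (Fisher's exact test with Benjamini-Hochberg adjustment, 247 at an unadjusted p under 0.05). Of the 241, 155 were on more often in milestone cultivars and 86 more often in soyNAM parents. The rule pools the collections, so a gene on in 1 collection and off in the other enters the list by that difference alone. The list was thus chosen in part for what the test asks, and no conclusion is drawn from the 241. A batch that coincides with the collection cannot be told apart here either. The genes that varied most between accessions were Glyma.19G046600, on at that level in 13 of 41 soyNAM parents and 30 of 61 milestone cultivars and reaching 8295 FPKM, and Glyma.19G046800, on in 13 and 29 and reaching 7755 FPKM. Within 1 collection, with 5 accessions on each side, 229 genes switched among soyNAM parents and 410 among milestone cultivars. Of these, 148 switched in both. Independent lists among the 29635 genes that reached 5 FPKM in any library would share 3.17. That pool includes genes on in every library, which cannot switch, so 3.17 is too low and no conclusion is drawn from it. Over all genes of the table, whether switch-like by the rule above or not, 4 reached 1 FPKM in all milestone cultivars and stayed below 0.1 FPKM in all soyNAM parents, and 0 genes did the reverse.

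A hypothesis was that neighbouring genes switch together, as a segment present in some accessions and absent in others could bring about. Among the 148 genes that switched in both collections, 9 pairs had adjacent IDs, taken as the order along the chromosome. Random sets of as many genes had 0.415 pairs on average and at most 5 in 10000 draws (p = 1e-04, the smallest the draws can give). The sets came from all genes that reached 5 FPKM in any library, variable or not, so a clustering of variable genes as such was not set apart. In 8 of the 9 pairs the on and off states at 1 FPKM agreed, with phi coefficients of at least 0.907 over all libraries, 0.906 within soyNAM parents and 0.865 within milestone cultivars, where random pairs of these genes had a median of 0.00298 over all libraries. The pair Glyma.06G252700 and Glyma.06G252800 did not, at 0.169 over all libraries. Presence of the genes in the DNA was not measured, and paralogs next to each other that share reads would also give adjacent pairs.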
